A study of Mus musculus with 11 samples.

How the data were processed

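The series profiled mouse models driven by the ZFTA-RELA fusion, the defining oncogene of a form of supratentorial ependymoma, by single-cell RNA sequencing with TrackerSeq, a method that also tags cell lineages. Per the labels, 11 libraries were made on the 10x Chromium platform, 1 from a P4 brain (IUE-ZR-1) and 10 from tumours given 5 numbers. IUE-ZR-2 and IUE-ZR-6 have 1 library each, IUE-ZR-3 and IUE-ZR-4 have 3 each, and IUE-ZR-5 has 2. IUE is read here in its usual meaning in this field, in utero electroporation, and the meaning of P4 is not spelled out in the sources used here. Tissue was dissociated with an enzymatic brain tumour kit and live GFP-positive cells were sorted before loading, per the labels' protocols. Libraries with the same number share a code with a letter added in their titles, such as Z12a, Z12b and Z12c for IUE-ZR-3. The labels do not say whether they come from separate animals or are parts of a single tumour. P-values between libraries therefore measure the spread between libraries only, which may be technical. Each pairwise comparison may set a single tumour against another.

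The deposited tables hold counts of unique molecular identifiers (UMIs) per gene and cell barcode, as whole numbers without normalization, made with Cell Ranger 9.0.0 on mm10 per the submitters' processing notes. The release of the gene annotation is not given in the sources used here. All 11 tables list the same 32285 genes. Of these, 32158 (99.6%) were matched by Ensembl identifier to a mouse annotation of the same build, which gave the coordinates. Lineage barcodes, the fusion transcript and GFP were not analysed here. No row carries the symbol Zfta, so that gene was not analysed here.

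Barcodes were kept with at least 1000 UMIs, at least 500 genes and under 15% mitochondrial UMIs. Doublet scores were computed per library with Scrublet in Scanpy 1.11.5, and the highest scores were removed at 0.8% per 1000 barcodes. Scrublet's automatic threshold, which was not used, marked 0 to 41 barcodes per library. Counts were scaled to 10000 per cell and log transformed, and 2000 variable genes gave 30 principal components, a graph of 15 neighbours and Leiden clusters at resolution 1 (leidenalg 0.10.2), without integration. Ribosomal protein genes and 14 of the 16 gene lists were left out of the variable genes, so that these lists could be compared between clusters. A cluster was called "X-like" only where at least 3 markers of 1 of 16 fixed marker lists stood among its 100 leading genes. Names were withheld where another type had more than 0.5 times as many markers there, or more markers than the named type among the 10 leading genes. They were also withheld where the cluster's median UMI count lay under its library median divided by 3 and the 10 leading genes held no marker of the type or a marker of another type. The marker lists were astroglial, ependymal, neuronal, interneuron, intermediate progenitor, oligodendrocyte precursor, oligodendrocyte, choroid plexus, microglia or macrophage, T or NK cell, B cell, neutrophil, endothelial, mural, fibroblast and erythroid. Neural cells are all cells outside clusters named immune, vascular, fibroblast or erythroid, and so include the unnamed clusters. That group holds cluster 1, with 4331 cells of IUE-ZR-3 at a low median of 1310 UMIs and macrophage and endothelial markers among its genes. It also holds cluster 8, with 1873 of the 3062 neural cells of IUE-ZR-6 at a median of 1200 UMIs. Haemoglobin genes led that cluster, and 7 macrophage markers stood among its 100 leading genes.

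Counts of neural cells were summed and tested with edgeR 4.0.16 (quasi-likelihood test, TMM scaling, Benjamini-Hochberg adjustment) in R 4.3.3. The first comparison used 1 sum per number, 5 tumours against the P4 brain, at an adjusted p under 0.05. With 1 P4 library, its spread is assumed to equal that of the tumours. The P4 brain carries an IUE-ZR number and had a sort for GFP like the tumours. Whether its cells carry the fusion was not analysed here, so it is not read as a fusion-free control. The pairwise comparisons used 8 libraries of IUE-ZR-3, IUE-ZR-4 and IUE-ZR-5 in 1 fit, at an adjusted p under 0.05 and a log2 fold change of at least 1 in size. Neural classes were compared with the other neural cells of the same tumour, with the tumour as a block, over 12 gene lists left out of the clustering. That comparison was planned for classes with at least 50 cells in at least 4 tumours. No class met this, and the rule was relaxed to at least 20 cells in at least 3 tumours after the data were seen. Gene lists were tested with camera in limma 3.58.1 at a preset correlation of 0.01 and again with an estimated correlation. The 15 lists tested were S phase, G2M phase, ZFTA-RELA ependymoma genes, NF-kB targets, PLAG family and imprinted genes, Notch pathway, hypoxia and glycolysis, dissociation and stress, interferon response, MHC class I, mesenchymal and matrix, dorsal telencephalon, ventral telencephalon, cholesterol synthesis and mitochondrial transcripts. A list of sex-linked genes was described without this test. Counts of passing list members are to be read against the share of all genes that passed in the same comparison. Class shares and the share of cells with G2M transcripts were compared between the 3 numbers with an exact permutation of the library labels on the F ratio, taking its upper tail (560 arrangements). A cell counted towards the G2M share with at least 3 UMIs of that list after thinning to 2000 UMIs.

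Levels are given as CPM of the neural sum, as mean ± SD over libraries or tumours. A group at 0 is set against a floor of 3 counts in its summed UMIs, which gives 0.434 CPM for the P4 brain and 0.0167 to 0.137 CPM for the tumours. Intervals are exact at 95% (Clopper-Pearson for shares, Poisson-based for ratios) and cover counting error only. Named genes are the 12 largest changes in each direction among passing genes with at least 20 CPM and no overlap between the groups, up to 4 members per list, and Rela, Ccnd1 and L1cam. Other genes named in the text, such as those of macrophage-like cells and further list members, were chosen after their values were seen. Deposited totals ran from 7173022 UMIs (P4 brain) to 87457625 UMIs, and neural sums from 6917985 UMIs (P4 brain) to 179397389 UMIs (IUE-ZR-3). On simulated counts the P4 comparison recovered 0% of genes changed by a log2 fold of 1 or 2, 17.5% at 3, 62.5% at 5 and 95.0% at 8, with 1 false call among 21503 unchanged genes. The folds of 5 and 8 were added after the smaller ones gave few calls. The pairwise comparisons recovered 40.0% to 55.0% at a log2 fold of 1 and 100.0% at 2 or more, with 4 to 6 false calls among 20473 unchanged genes. For the oligodendrocyte precursor-like, oligodendrocyte-like and astroglial-like classes, 82.5%, 85.0% and 30.0% were recovered at a log2 fold of 2.

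Alternatives were DESeq2 1.42.0, its size factors in edgeR, no filter on low counts, stricter cell filters, doublets kept, all cells, a single neural class, sums thinned to the P4 total, other Leiden resolutions, genes centred within each number, a test against a minimum fold (glmTreat), fry, the replicate number as a block, and each tumour or library left out. Libraries of the same number differed by more than sampling noise (chi-square per degree of freedom 2.87 to 26.2), so none was treated as deposited more than once. SciPy 1.17.1, pandas 2.3.3, NumPy 2.4.6 and matplotlib 3.10.9 under Python 3.11.15 were used for the other steps.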

Results

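Single-cell transcriptomes were collected from 1 P4 brain and 5 numbered tumours of the ZFTA-RELA mouse model, 11 libraries in all. The tables held 824 barcodes for the P4 brain and 3569 to 7488 barcodes per tumour library, of which 5 libraries held exactly 5000. After filtering, 476 cells of the P4 brain and 2781 to 6678 cells per tumour library remained. Depth differed widely, with a median of 1423 UMIs per kept cell in IUE-ZR-6, 5537 in the P4 brain and 26412 in replicate 1 of IUE-ZR-5. The comparisons below ask how tumour cells differ from those of the P4 brain, how the tumours differ from each other, and how cell classes within a tumour differ.

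The cell composition differed between tumours although all libraries came from a sort for GFP. Microglia or macrophage-like cells made up 78.1% ± 1.14 (SD, n = 3 libraries) of IUE-ZR-4, against 8.22% ± 1.15 (n = 3) of IUE-ZR-3 and 8.56% ± 0.0478 (n = 2) of IUE-ZR-5. In the single libraries of IUE-ZR-2 and IUE-ZR-6 their shares were 2.15% (95% interval 1.74 to 2.63) and 17.0% (15.9 to 18.2). Unnamed clusters with macrophage markers are not counted, namely cluster 1 (4331 of 12631 cells of IUE-ZR-3) and cluster 8 (1873 of 3896 cells of IUE-ZR-6). None was found among 476 cells of the P4 brain, which allows a share of up to 0.772%. Astroglial-like cells held 26.2% ± 1.55 of IUE-ZR-5 and 0.151% ± 0.0832 and 0.121% ± 0.0842 of IUE-ZR-3 and IUE-ZR-4. Oligodendrocyte precursor-like cells held 3.88% ± 0.293 of IUE-ZR-5 and 0.232% of IUE-ZR-4, and none was found among 12631 cells of IUE-ZR-3. Oligodendrocyte-like cells held 3.27% of IUE-ZR-5, 0.187% of IUE-ZR-4 and 0.0788% of IUE-ZR-3. These shares depend on the clustering. In IUE-ZR-5 the 1596 astroglial-like cells became 2008 at resolution 0.5, 2057 with doublets kept, 567 at resolution 2 and 216 with genes centred within each number. Its 236 oligodendrocyte precursor-like cells became 685 at resolution 0.5 and 512 with doublets kept, where IUE-ZR-3 held 18 and 12, and its 198 oligodendrocyte-like cells became 53 and 52 at resolutions 0.5 and 2. Neuronal-like cells dominated the P4 brain with 61.8% (57.2 to 66.2) and reached 0.883% ± 0.130 in IUE-ZR-5 and 1.98% in IUE-ZR-6.

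Vascular and other immune cells varied too. Endothelial-like cells held 4.36% ± 2.02 of IUE-ZR-3, 0.494% ± 0.0420 of IUE-ZR-4 and 3.37% ± 0.539 of IUE-ZR-5, and mural-like cells 0.880%, 0.0354% and 0.115%. Neutrophil-like cells held 1.80% of IUE-ZR-4, and T or NK cell-like cells held 0.977% ± 0.0300 there, 0.0700% in IUE-ZR-3 and 0.173% in IUE-ZR-5. All 9 classes differed between the 3 numbers with replicate libraries (exact permutation test, adjusted p 0.0161 to 0.0357). All these shares are of all kept cells, so the 15504 macrophage-like of 19850 cells in IUE-ZR-4 lower every other share there. The 9 tests are therefore not independent, and gaps of other classes to IUE-ZR-4 are smaller among cells that are not macrophage-like. Most remaining cells fell into unnamed clusters, which held 93.1% of IUE-ZR-2, 86.2% ± 3.21 of IUE-ZR-3, 18.1% of IUE-ZR-4 and 53.5% of IUE-ZR-5. They held 73.8% of IUE-ZR-6 and 29.6% of the P4 brain. Without 1 library of IUE-ZR-4 as few as 3 classes passed, and without 1 library of IUE-ZR-3, 7 or 8. These tests had 210 arrangements instead of 560, so part of the drop may come from the smaller test. Leaving out a library of IUE-ZR-5 leaves 1 there, and no count is read from that.

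**Figure D1:**
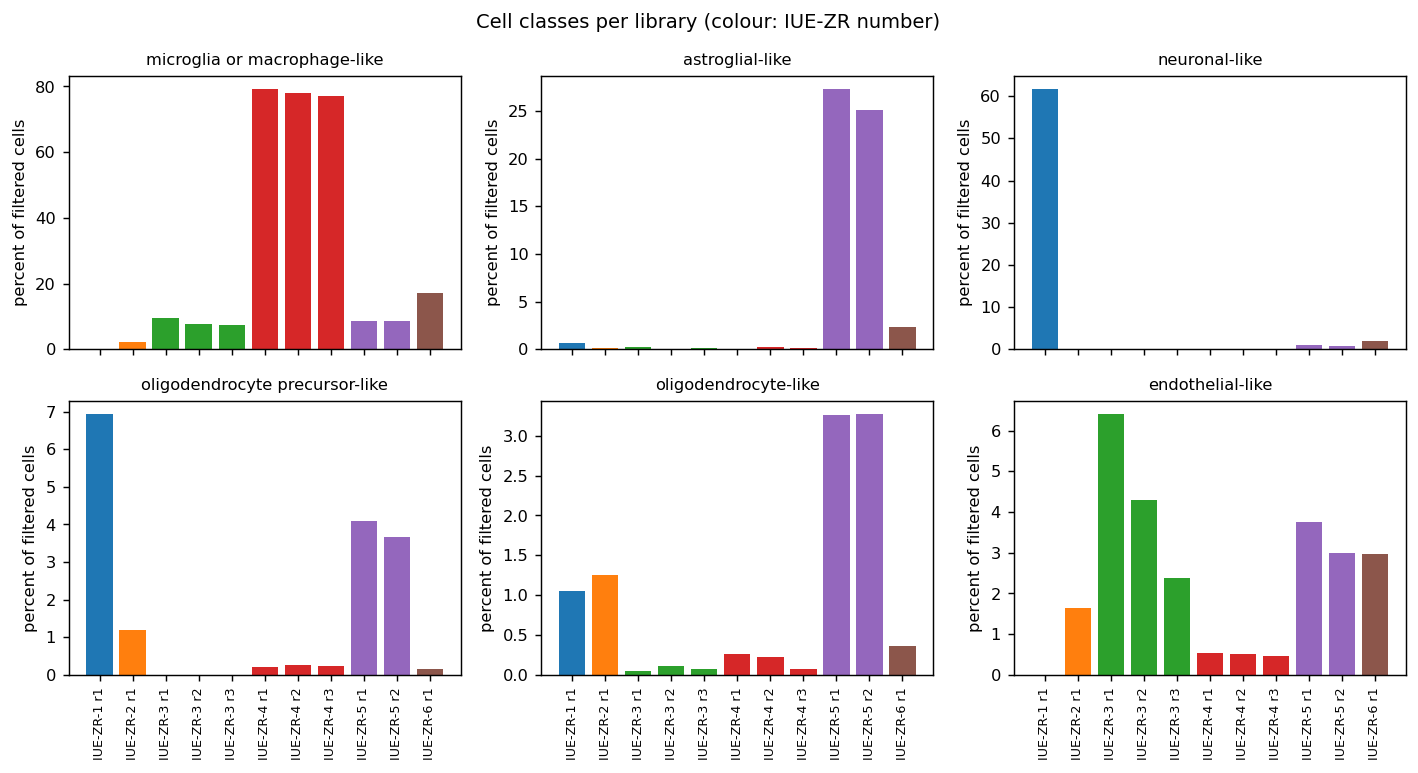
Percent of filtered cells in 6 classes for each of the 11 libraries, 1 bar per library, coloured by IUE-ZR number, with a separate vertical scale per class that starts at 0. The macrophage-like bars of IUE-ZR-4 average 78.1%, the astroglial-like bars of IUE-ZR-5 average 26.2%, and the neuronal-like bar of the P4 brain reaches 61.8%.

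Genes that differed between neural cells of the 5 tumours and those of the P4 brain included single matrix and interferon-inducible genes that were higher, and single neuronal genes that were lower. No gene list kept its camera call with an estimated correlation. Cdkn2a, a locus of cell cycle inhibitors, averaged 395 ± 175 CPM (SD, n = 5 tumours) against 1.16 CPM in the single P4 library. Bst2, an interferon-inducible antiviral membrane protein, averaged 137 ± 31.2 against 0.723 CPM, and fibronectin (Fn1) 458 ± 216 against 3.90 CPM. In the other direction Tbr1, a transcription factor of early projection neurons, stood at 0.4003 ± 0.298 against 54.1 CPM, and Cdh8, a neuronal cadherin, at 2.25 ± 0.988 against 380.0 CPM. In edgeR 175 of 21703 genes passed, 94 higher and 81 lower in the tumours, and 5186 had an unadjusted p under 0.05. The single P4 library cannot be told apart from its batch, and the median of all genes stood at a log2 fold change of 0.23 (0.22 with DESeq2 size factors). Neuronal-like cells made up 61.8% of the P4 cells and at most 1.98% of those of a tumour. Lower neuronal genes may therefore reflect which cells were summed. The count depends on the tumours and the tool: 0 genes passed in edgeR without IUE-ZR-3, IUE-ZR-4 or IUE-ZR-5 (4616, 4974 and 4298 at an unadjusted p under 0.05), 4 without IUE-ZR-2, 1178 without IUE-ZR-6, and 3410 in DESeq2 with all 5.

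Several of the genes with the largest increase were at or near 0 in the P4 brain. Decorin (Dcn), a matrix proteoglycan, averaged 140 ± 94.2 CPM and was at least 324-fold higher, and the small heat shock protein Hspb1, at 85.4 ± 31.0 CPM, at least 197-fold higher. H2-Q4, an MHC class I gene, averaged 34.0 CPM and was at least 78.3-fold higher. Nid1, a basement membrane protein, was 417-fold higher (counting interval 115 to 3441) and Timp1, a metalloproteinase inhibitor, 158.5-fold (43.9 to 1309). The protease inhibitor A2m stood at 360.0 ± 162 against 2.60 CPM and the zinc finger gene Bnc2 at 206 ± 108 against 1.45 CPM. All of these were above the P4 brain in 5 of 5 tumours, which the choice of named genes without overlap required. Of the 21703 genes tested, 13613 had no overlap between the groups. Genes that fell included Cntnap5a, a neuronal adhesion gene (0.541 ± 0.232 against 172 CPM, log2 fold change -8.15 ± 0.453 SE, edgeR adjusted p 0.0124), the synaptic scaffold gene Ppfia2 (16.7 ± 8.23 against 784 CPM), the glycine receptor subunit Glra2 (0.0826 against 82.7 CPM), Snhg11 (0.173 against 61.0 CPM) and the ephrin receptor Epha6 (1.84 against 203 CPM). These lower levels of neuronal genes may follow from the many neuronal-like cells in the P4 sum rather than from a change within tumour cells. In mm10, Cdkn2a (ENSMUSG00000044303) lies on chromosome 4 from 89274471 to 89294653, Bst2 (ENSMUSG00000046718) on chromosome 8 from 71534255 to 71537456, and Cntnap5a (ENSMUSG00000070695) on chromosome 1 from 115684756 to 116587323.

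Among the 15 fixed lists, mesenchymal and matrix genes had the most passing members over all genes, with 4 of 15 higher in the tumours and 13 when adjusted over the list alone. These were Fn1, Timp1, Lgals1 (420 ± 128 against 17.4 CPM) and Anxa2 (84.2 ± 33.2 against 2.75 CPM). The list's camera adjusted p was 8.2e-13 at the preset correlation and 0.0523 with an estimated correlation. NF-kB targets had 2 of 18 higher (11 over the list alone), Icam1 (149 ± 22.3 against 3.76 CPM) and Bcl3 (47.8 against 1.01 CPM), with p 7.5e-08 and 0.191 with an estimated correlation. For the interferon response 1 of 16 passed (13 over the list alone), Bst2, with a median log2 fold change of 5.55, or 5.30 with genes at 0 set to their bound, and p 2.8e-13 against 0.186 with an estimated correlation. None of 10 MHC class I genes passed over all genes and 10 did over the list alone. Their median was 5.69, also with the gene at 0 set to its bound, and camera gave p 2.8e-13 against 0.186 with an estimated correlation. B2m stood at 621 ± 275 against 10.6 CPM and H2-D1 at 456 ± 237 against 16.8 CPM. Markers of microglia or macrophages lay higher in the same sums, with 0 of 16 passing and 12 over the list alone (camera p 3.3e-08, 0.419 with an estimated correlation). C1qa averaged 65.5 CPM in neural cells of the tumours and 0 in the P4 brain, where no macrophage-like cell was found.

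Stress and hypoxia genes had 0 passing members over all genes. Over the list alone 12 of 16 dissociation and stress genes and 3 of 18 hypoxia and glycolysis genes passed, with medians of 3.13 and 1.53 and camera p 3.3e-09 and 5.6e-04 (0.186 and 0.363 with an estimated correlation). Jun averaged 407 ± 36.3 against 85.9 CPM and Vegfa 215 ± 67.2 against 32.4 CPM. Mitochondrial transcripts had 0 of 13 passing, a median of 1.33 and camera p 9.3e-04 (0.387 with an estimated correlation). Dorsal telencephalon genes had 1 of 14 lower, Tbr1 (4 over the list alone, camera p 9.6e-06, 0.186 with an estimated correlation). Ventral telencephalon genes had 0 of 11 passing and 7 over the list alone, with a median of -5.79 and camera p 3.3e-09 (0.194 with an estimated correlation). Notch pathway genes had 0 of 13 passing and 6 over the list alone, with a median of -0.50 and camera p 0.0103 (0.194 with an estimated correlation). Dll1, a Notch ligand, stood at 1.74 ± 1.06 against 28.8 CPM. S phase, G2M phase, ZFTA-RELA ependymoma, PLAG family and imprinted, and cholesterol synthesis genes did not pass camera (adjusted p 0.564, 0.238, 0.137, 0.165 and 0.669), and the S phase median of 0.08 and its test differed in sign. None of their genes passed over all genes in edgeR, and 0, 0, 1, 0 and 1 passed over the list alone.

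Neuronal markers had 0 of 19 passing and 16 over the list alone (camera p 2.7e-11, 0.419 with an estimated correlation), such as Dcx, at 10.3 ± 13.5 against 362 CPM. Interneuron markers had 0 of 10 and 7 over the list alone (p 1.9e-08, 0.419). Intermediate progenitor markers had 2 of 11 lower, the somatostatin receptor Sstr2 (2.02 ± 1.52 against 59.1 CPM) and the RNA-binding protein gene Elavl2 (8.03 ± 4.76 against 200.2 CPM), with p 4.9e-05 (0.465). Oligodendrocyte precursor markers had 0 of 13, with p 0.0136 for lower levels (0.578), endothelial markers 0 of 10 with p 0.0075 for higher levels (0.578), and fibroblast markers 1 of 8, Dcn, with p 0.0020 (0.419). The second value in each pair is the adjusted p with an estimated correlation. Astroglial, ependymal, oligodendrocyte, choroid plexus, T or NK cell, B cell, neutrophil, mural and erythroid markers did not pass camera (adjusted p 0.0591 to 0.939).

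The genes tied to the fusion and to this tumour type did not pass in this comparison. The P4 cells were sorted for GFP too and may carry the fusion, so this does not set tumour against normal brain. On simulated counts the comparison recovered 0% of genes at a log2 fold of 1 or 2 and 17.5% at 3, so these genes may still differ. Ccnd1, which encodes cyclin D1, averaged 573 ± 168 against 253 CPM (edgeR adjusted p 0.219), and Vim 1482 ± 479 against 167 CPM (0.0748). Rela, whose product is the NF-kB subunit p65, averaged 47.7 ± 8.22 against 47.1 CPM (0.734). Whether that row also counts fusion transcripts is not given in the sources used here. L1cam, an adhesion molecule used as a marker of human ZFTA-fused ependymoma, stood at 1.55 ± 1.51 against 15.3 CPM (0.148). Rela (ENSMUSG00000024927) lies on chromosome 19 from 5637483 to 5648130, L1cam (ENSMUSG00000031391) on chromosome X from 73853778 to 73896105, and Ccnd1 (ENSMUSG00000070348) on chromosome 7 from 144929931 to 144939925. Sex-linked genes separated the samples but none of the 6 passed. Xist, the RNA that silences an X chromosome, stood at 1083 CPM in the P4 brain, 355 in IUE-ZR-3 and 494 in IUE-ZR-6, against at most 0.209 CPM in the other tumours. The Y-linked gene Ddx3y stood at 80.0, 67.1 and 85.7 CPM in IUE-ZR-2, IUE-ZR-4 and IUE-ZR-5.

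**Figure D2:**
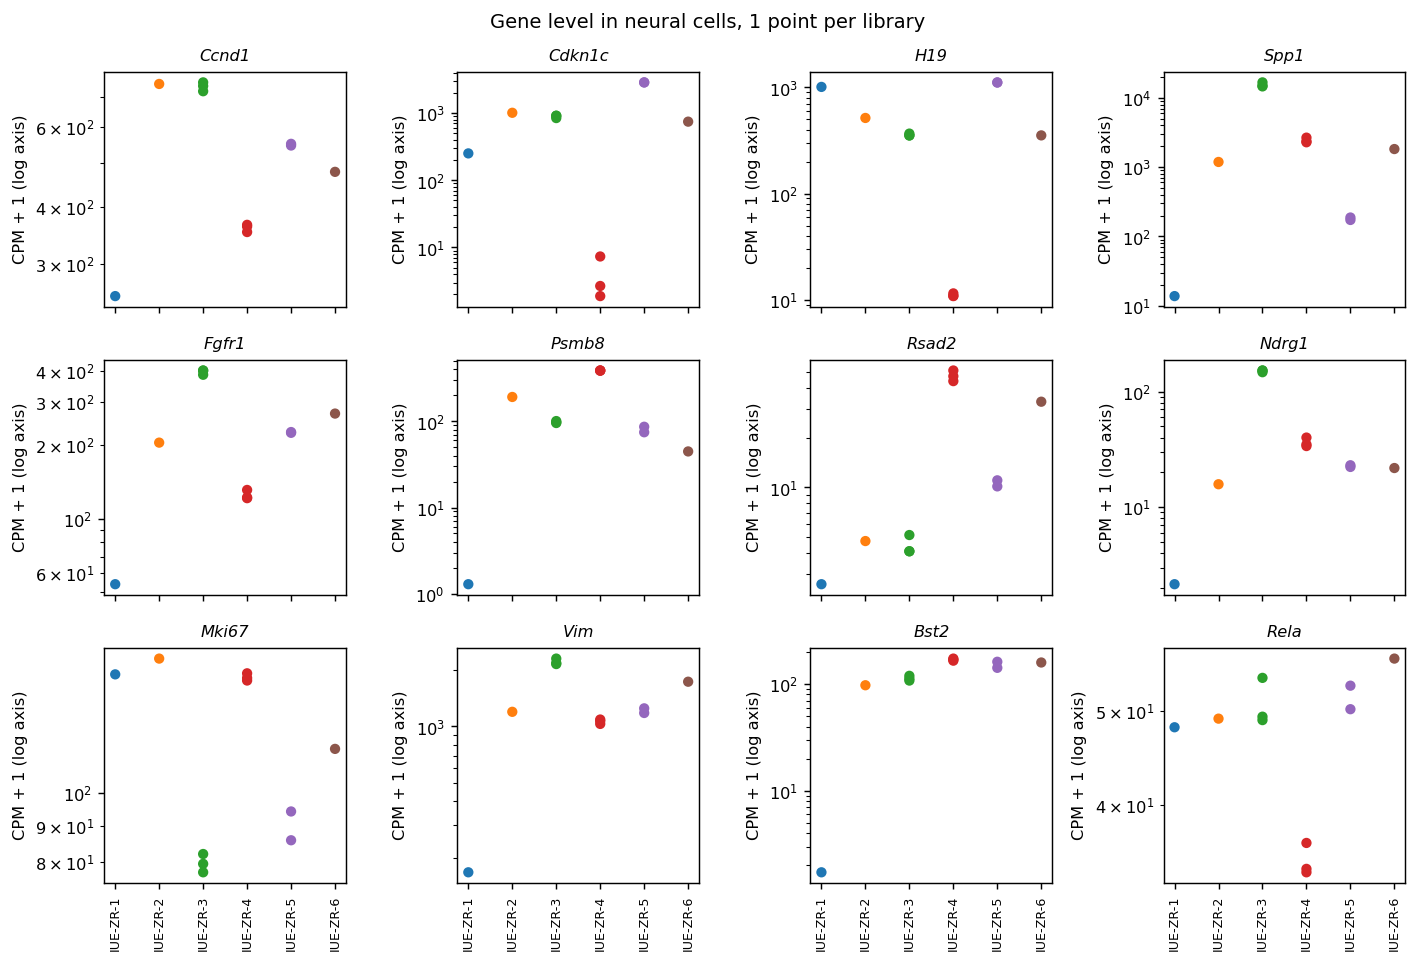
CPM plus 1 on a log axis for 12 genes in neural cells, with 1 point per library grouped by IUE-ZR number and a separate axis range per gene. Cdkn1c and H19 are lowest in IUE-ZR-4 (means 2.97 and 10.1 CPM), and Spp1 is highest in IUE-ZR-3 (15483 CPM).

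Between neural cells of IUE-ZR-3 and IUE-ZR-4, 14 of 18 hypoxia genes and 10 of 16 stress genes were higher in IUE-ZR-3, 9 of 16 interferon genes were lower, and chromosome 7 transcripts were lower in IUE-ZR-4. No gene list kept its camera call with an estimated correlation in the 3 comparisons of tumours. Cdkn1c, a cell cycle inhibitor expressed from the maternal copy, stood at 886.5 ± 39.9 CPM (n = 3) in IUE-ZR-3 and 2.97 ± 2.95 CPM (n = 3) in IUE-ZR-4. The heparan sulfate sulfotransferase gene Hs6st3 went the other way, with 9.20 ± 2.32 against 1403 ± 44.0 CPM. Osteopontin (Spp1), a secreted matrix protein, stood at 15483 ± 1117 against 2436 ± 202 CPM, and the vasodilator peptide gene Adm, a hypoxia target, at 55.9 ± 1.34 against 0.477 ± 0.283 CPM. In edgeR 6504 of 20673 genes passed, 3395 higher and 3109 lower in IUE-ZR-3. With glmTreat, which tests against the fold itself, 4211 passed. Of the 1536 genes tested on chromosome 7, 637 were higher and 135 lower in IUE-ZR-3 (50.3%, against 29.96% on other chromosomes). The list counts, the hypoxia list included, were not corrected for this. Members on chromosome 7 may therefore add to those higher in IUE-ZR-3. The chromosome 7 median in neural cells of IUE-ZR-4, against the mean of IUE-ZR-3 and IUE-ZR-5, was -0.90 ± 0.032 (log2, n = 3 libraries), and in its macrophage-like cells -0.07 ± 0.019.

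**Figure D3:**
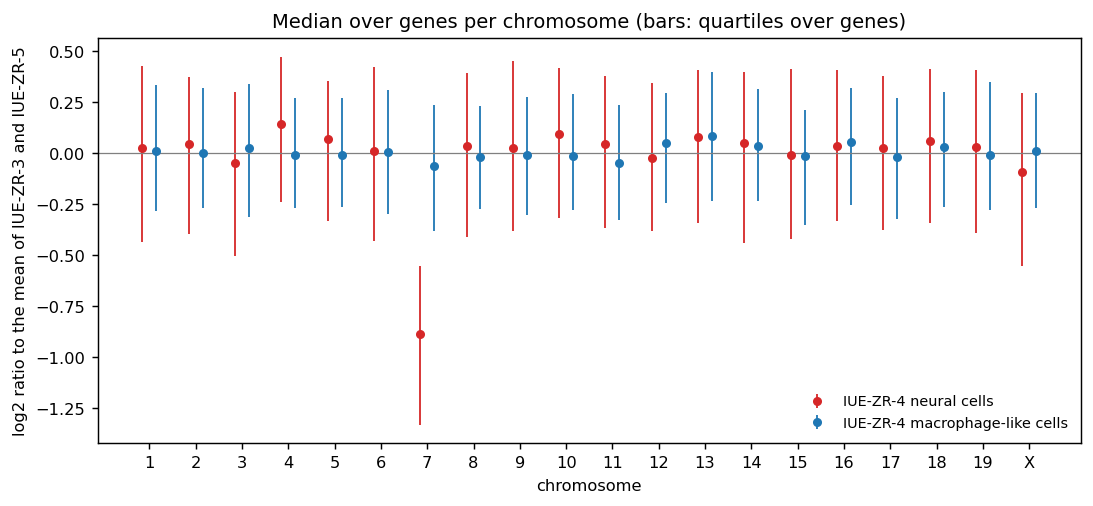
Median log2 ratio of IUE-ZR-4 to the mean of IUE-ZR-3 and IUE-ZR-5 over the genes of each chromosome, for neural and macrophage-like cells, with bars from the lower to the upper quartile over genes. Chromosome 7 of the neural cells stands apart, while the other autosome that moves most there lies at 0.14 and chromosome 7 of the macrophage-like cells lies at -0.07.

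The transporter gene Slc47a1 was at 127 ± 1.71 CPM in IUE-ZR-3 and 0 in IUE-ZR-4, at least 2032-fold apart. Higher in IUE-ZR-3 were also the homeobox gene Gsc (62.8 ± 4.53 against 0.762 CPM), the growth factor gene Fgf3 (96.3 against 1.45 CPM), Hpse2 (70.1 against 0.994 CPM) and the sodium channel gene Scn7a (105 against 2.05 CPM). Higher in IUE-ZR-4 were the transcription factor genes Tlx1 (76.1 against 0.0224 CPM, log2 fold change -11.28 ± 0.213 SE, edgeR adjusted p 6.9e-11), Pax2 (42.1 against 0.0228 CPM), Tcf21 (57.9 against 0.467 CPM) and Gata4 (125 against 2.29 CPM). The chemokine gene Cxcl15 (472 ± 34.7 against 4.13 CPM) and the cadherin gene Cdh3 (96.3 against 1.11 CPM) were higher there too. In mm10, Cdkn1c (ENSMUSG00000037664) lies on chromosome 7 from 143458339 to 143461050, Slc47a1 (ENSMUSG00000010122) on chromosome 11 from 61343401 to 61378345, Hs6st3 (ENSMUSG00000053465) on chromosome 14 from 119138341 to 119869815 and Tlx1 (ENSMUSG00000025215) on chromosome 19 from 45150680 to 45156943.

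Hypoxia and glycolysis genes had 14 of 18 higher and 1 lower in IUE-ZR-3 (15 over the list alone, median 1.39), among them Ndrg1 (149 ± 2.93 against 35.2 ± 3.30 CPM) and Bnip3 (37.9 ± 2.55 against 4.22 ± 0.529 CPM), with camera p 1.4e-13 and 0.128 with an estimated correlation. Dissociation and stress genes had 10 of 16 higher (10 over the list alone), such as the immediate early genes Fos (736 ± 36.9 against 237 ± 7.05 CPM) and Ier2 (528 against 157 CPM), with p 3.8e-06 and 0.329 with an estimated correlation. Interferon response genes had 9 of 16 lower and 2 higher (11 over the list alone), with the antiviral gene Rsad2 at 3.45 ± 0.602 against 46.4 ± 3.53 CPM. The median was -1.04, with p 1.6e-04 and 0.279 with an estimated correlation. MHC class I genes had 3 of 10 lower (3 over the list alone), the proteasome subunit gene Psmb8 (97.0 ± 2.58 against 388 ± 1.13 CPM), the class I regulator Nlrc5 (7.98 against 25.9 CPM) and the peptide transporter gene Tap1 (14.2 against 35.5 CPM), with p 0.0028 and 0.415 with an estimated correlation. Macrophage markers had 1 of 16 higher and 3 lower in IUE-ZR-3 in the same sums, where C1qa stood at 93.2 ± 44.1 against 72.0 ± 7.69 CPM and Cd74 at 63.5 against 245 CPM.

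G2M genes had 5 of 25 lower (5 over the list alone), such as the mitotic kinase gene Aurka (12.7 ± 0.759 against 46.0 ± 1.07 CPM) and the kinesin gene Cenpe (38.9 against 112 CPM), with p 8.5e-07 and 0.199 with an estimated correlation. S phase genes had 3 of 25 lower (3 over the list alone), such as Clspn (13.1 ± 1.23 against 65.2 ± 1.34 CPM). Their camera p was 1.2e-06, and 0.279 with an estimated correlation. Of all genes tested, 3109 of 20673 were lower, so the counts of the G2M and S phase lists lie near that share. NF-kB targets had 6 of 18 lower (6 over the list alone), with the adhesion gene Vcam1 at 8.75 against 72.5 CPM and the cytokine gene Il6 at 0.206 against 7.26 CPM, p 0.0322 and 0.262 with an estimated correlation. Cholesterol synthesis genes had 6 of 15 higher (Fdps at 150.4 against 77.6 CPM; p 1.2e-04, 0.329 with an estimated correlation) and mitochondrial transcripts 5 of 13 higher (p 0.0103, 0.445 with an estimated correlation).

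The other gene lists did not pass camera but held passing genes. ZFTA-RELA ependymoma genes had 5 of 15 higher and 3 lower in IUE-ZR-3 (p 0.704), with Ccnd1 at 737 ± 16.6 against 359 ± 6.83 CPM, Fgfr1 at 395 against 124 CPM and Vim at 2207 against 1062 CPM. Ccnd1 lies on chromosome 7. PLAG family and imprinted genes had 6 of 16 higher and 3 lower (p 0.345), with H19, a maternally expressed RNA, at 356 ± 8.27 against 10.1 ± 0.360 CPM and Peg3 at 51.1 against 283 CPM. The medians of these 2 lists, -0.13 and -0.21, differed in sign from their tests. Notch pathway genes had 4 of 13 higher (p 0.0772), with Hes1 at 132 against 37.5 CPM, and mesenchymal and matrix genes 4 of 15 higher and 1 lower (p 0.134), with Serpine2 at 177 against 32.7 CPM. Dorsal telencephalon genes had 6 of 14 higher and 2 lower (p 0.817), with Bcl11b at 6.18 against 62.9 CPM. Ventral telencephalon genes had 3 of 7 higher (p 0.658, median 1.02, or 0.26 with genes at 0 set to their bound). Astroglial markers had 8 of 18 higher and 1 lower (p 7.9e-04, 0.653 with an estimated correlation), and neuronal markers 10 of 19 lower (p 0.0155, 0.822 with an estimated correlation). No other marker list passed camera. Endothelial markers had 6 of 10 higher, and oligodendrocyte precursor markers 5 of 13 higher and 7 lower. Sex-linked genes passed at 6 of 6, with Xist at 356 against 0.202 CPM. Rela stood at 49.8 ± 2.89 against 34.0 ± 1.35 CPM (log2 fold change 0.86, under the threshold of 1), and L1cam at 0.235 against 0.527 CPM (edgeR adjusted p 0.125).

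Compared with IUE-ZR-5, neural cells of IUE-ZR-3 had 10 of 18 hypoxia genes higher, and 17 of 19 neuronal and 10 of 13 oligodendrocyte precursor markers lower. Spp1 stood at 15483 ± 1117 CPM (n = 3) against 179 ± 10.3 CPM (n = 2), and matrix Gla protein (Mgp), a calcification inhibitor, at 1712 ± 107 against 43.5 ± 5.18 CPM. Lower in IUE-ZR-3 were Lhfpl3, an oligodendrocyte precursor marker (7.01 ± 4.05 against 547.5 ± 21.6 CPM), the imprinted gene Nnat (10.4 ± 3.54 against 650 ± 77.3 CPM) and Igfbpl1 (2.92 against 211 CPM). In edgeR 4997 of 20673 genes passed, 1879 higher and 3118 lower in IUE-ZR-3, and 3178 passed with glmTreat. The beta-defensin gene Defb19 was at 0 in IUE-ZR-3 and at 46.2 ± 5.93 CPM in IUE-ZR-5, at least 2781-fold apart. Slc47a1 (127 against 0.266 CPM), the proteoglycan gene Srgn (420 ± 33.5 against 13.2 CPM) and the matricellular gene Ccn2 (80.6 ± 14.8 against 3.29 CPM) were higher in IUE-ZR-3, and Aard (1.63 against 227.5 CPM) was lower. In mm10, Spp1 (ENSMUSG00000029304) lies on chromosome 5 from 104435118 to 104441050, Mgp (ENSMUSG00000030218) on chromosome 6 from 136872435 to 136875823 and Defb19 (ENSMUSG00000050645) on chromosome 2 from 152576086 to 152580312.

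Hypoxia and glycolysis genes had 10 of 18 higher and 1 lower in IUE-ZR-3 (11 over the list alone), with Ndrg1 at 149 against 21.7 CPM and Adm at 55.9 against 7.82 CPM (camera p 1.9e-12, 0.116 with an estimated correlation). Stress genes had 7 of 16 higher, with Ier3 at 100.5 against 27.3 CPM and Btg2 at 293 against 127 CPM (p 1.9e-04, 0.397 with an estimated correlation). Mesenchymal and matrix genes had 3 of 15 higher and 1 lower, among them Spp1 and the matrix glycoprotein gene Tnc (104 ± 3.19 against 9.31 ± 2.39 CPM), with p 2.6e-05 and 0.259 with an estimated correlation. Dorsal telencephalon genes had 8 of 14 lower, such as Bcl11b (6.18 ± 0.0263 against 35.8 ± 2.99 CPM) and Emx2 (1.17 against 14.6 CPM), with p 0.0272 and 0.297 with an estimated correlation. Ventral telencephalon genes had 5 of 7 lower and 1 higher, with p 0.0370 and 0.280 with an estimated correlation. PLAG family and imprinted genes had 7 of 16 lower and 1 higher, with Peg3 at 51.1 against 294 CPM and H19 at 356 against 1110.0 CPM (p 0.0370, 0.286 with an estimated correlation). NF-kB targets (2 of 18 higher; 0.259 with an estimated correlation), MHC class I (1 of 10 higher), cholesterol synthesis (0 of 15) and mitochondrial transcripts (4 of 13 higher) passed camera for higher levels in IUE-ZR-3, with p 0.0370, 0.0370, 0.0370 and 0.0202. For the last 3 the adjusted p with an estimated correlation was 0.494.

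S phase and G2M genes had 0 of 25 passing each in edgeR (camera p 0.543 and 0.110), Notch pathway genes 1 higher and 2 lower of 13 (0.649), ZFTA-RELA ependymoma genes 2 higher and 3 lower of 15 (0.914) and interferon response genes 1 higher and 5 lower of 16 (0.0855). The ubiquitin-like modifier gene Isg15 stood at 66.7 against 185 CPM, and Irf7 at 39.3 against 13.4 CPM. Neuronal markers had 17 of 19 lower (p 8.5e-18, 0.0317 with an estimated correlation) and oligodendrocyte precursor markers 10 of 13 lower (p 8.7e-13, 0.0317 with an estimated correlation), including Olig2 at 10.6 ± 2.17 against 65.0 ± 5.20 CPM. Oligodendrocyte markers had 10 of 10 lower (p 8.5e-05, 0.406), choroid plexus markers 4 of 5 (p 0.0012, 0.0808) and astroglial markers 7 of 18 (p 0.0297, 0.406), with the estimated-correlation p second. Macrophage markers had 12 of 16 higher in IUE-ZR-3 (p 2.7e-04, 0.506 with an estimated correlation), with C1qa at 93.2 against 11.8 CPM. Srgn and the stress list were higher in the same tumour as these markers. Spp1 was too, but macrophage-like cells of IUE-ZR-3 held only 2253 ± 228 CPM of it, against 15483 CPM in the neural cells. For Spp1 this argues against macrophage RNA as the main source. Sex-linked genes passed at 6 of 6. L1cam stood at 0.235 ± 0.128 against 2.25 ± 0.340 CPM (log2 fold change -2.98 ± 0.363 SE, edgeR adjusted p 4.2e-05) and Ccnd1 at 737 against 548 CPM (log2 fold change 0.70).

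Between neural cells of IUE-ZR-4 and IUE-ZR-5, 9 of 18 NF-kB targets and 5 of 10 MHC class I genes were higher in IUE-ZR-4, and 14 of 18 astroglial markers were lower, as were chromosome 7 transcripts. Cdkn1c stood at 2.97 ± 2.95 CPM (n = 3) against 2853 ± 3.12 CPM (n = 2), and H19 at 10.1 ± 0.360 against 1110.0 ± 2.97 CPM. Higher in IUE-ZR-4 were the cytokine gene Tnf (78.1 ± 5.77 against 2.08 CPM), the chemokine gene Cxcl3 (166 ± 12.4 against 3.82 CPM), the kininogen gene Kng2 (178 ± 5.72 against 2.67 CPM) and haptoglobin (Hp, 66.6 against 1.44 CPM). Lower were the glycoprotein gene Gpnmb (2.39 ± 0.447 against 345 ± 14.6 CPM), the apolipoprotein gene Apoc1 (0.443 against 60.6 CPM) and the lipogenic gene Thrsp (0.672 against 73.6 CPM). In edgeR 6508 of 20673 genes passed, 2594 higher and 3914 lower in IUE-ZR-4. Of the 1536 genes tested on chromosome 7, 97 were higher and 616 lower (46.4%, against 30.3% elsewhere). H19 (ENSMUSG00000000031) lies on chromosome 7 from 142575529 to 142578143 and Gpnmb (ENSMUSG00000029816) on chromosome 6 from 49036546 to 49070929.

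G2M genes had 8 of 25 higher in IUE-ZR-4, such as Aurka (46.0 ± 1.07 against 14.3 ± 0.433 CPM) and Bub1 (48.5 against 19.6 CPM), with camera p 4.0e-11 and 0.0738 with an estimated correlation. S phase genes had 7 of 25 higher, such as Tyms (112 ± 2.19 against 43.9 ± 0.332 CPM), with p 1.5e-08 and 0.193 with an estimated correlation. NF-kB targets had 9 of 18 higher, with the inhibitor gene Nfkbia at 122 ± 4.39 against 49.9 ± 0.473 CPM and the chemokine gene Cxcl1 at 43.0 against 4.01 CPM (p 6.0e-05, 0.0738 with an estimated correlation). MHC class I genes had 5 of 10 higher, with Psmb8 at 388 ± 1.13 against 79.7 ± 8.37 CPM and Psmb9 at 150.0 against 44.2 CPM (p 7.6e-07, 0.204 with an estimated correlation), and interferon response genes 3 of 16, with Rsad2 at 46.4 against 9.59 CPM (p 0.0217, 0.395 with an estimated correlation). Mesenchymal and matrix genes had 3 of 15 higher and 2 lower, with Anxa1 at 573 against 195 CPM (p 0.0118, 0.288 with an estimated correlation). Macrophage markers were higher for 14 of 16 in the same sums (p 2.6e-04, 0.509 with an estimated correlation), with Lyz2 at 79.4 ± 12.4 against 6.96 ± 2.61 CPM, so that these immune genes moved together with markers of the most abundant cells of IUE-ZR-4.

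PLAG family and imprinted genes had 7 of 16 lower and 1 higher in IUE-ZR-4 (p 0.0094, 0.193 with an estimated correlation), and cholesterol synthesis genes passed camera for lower levels with 0 of 15 genes passing (p 0.0292, 0.462 with an estimated correlation). Dorsal telencephalon genes had 8 of 14 lower (p 0.0574), such as Pax6 (5.52 against 35.1 CPM), and ventral telencephalon genes 5 of 7 (p 0.0541, median -3.79, or -2.61 with genes at 0 set to their bound). Notch pathway genes had 5 of 13 lower (0.169), hypoxia genes 7 of 18 lower and 2 higher (0.0710), stress genes 4 lower and 2 higher of 16 (0.182), ZFTA-RELA ependymoma genes 3 lower and 2 higher of 15 (0.694) and mitochondrial transcripts 0 of 13 (0.743). Astroglial markers had 14 of 18 lower (p 3.0e-10, 0.0767 with an estimated correlation), oligodendrocyte precursor markers 10 of 13 (p 3.9e-09, 0.0767), neuronal markers 15 of 19 with 1 higher (p 1.8e-05, 0.197) and oligodendrocyte markers 8 of 10 (p 0.0135, 0.509). Choroid plexus markers had 4 of 5 lower (p 0.0110, 0.197) and intermediate progenitor markers 7 of 11 (p 0.0030, 0.339). Of 6 sex-linked genes only Tsix passed. Counts over the list alone equal those over all genes for each of these lists.

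The share of neural cells with G2M transcripts differed between the 3 tumours. It was 38.1% ± 0.613 (n = 3) in IUE-ZR-4, 20.7% ± 1.83 (n = 3) in IUE-ZR-3 and 16.8% ± 0.0834 (n = 2) in IUE-ZR-5, an exact permutation p of 0.0071 over 560 arrangements. The P4 brain had 17.2% (95% interval 13.3 to 21.8), IUE-ZR-2 29.8% and IUE-ZR-6 31.5%. Thinning left out 157 of 476 P4 cells, 1764 of 4182 cells of IUE-ZR-2 and 2174 of 3062 cells of IUE-ZR-6, and between 33 of 1227 and 1633 of 3785 cells per library of the 3 other tumours. Unthinned shares were 76.8%, 64.8% and 64.8% in IUE-ZR-4, IUE-ZR-3 and IUE-ZR-5. The order of IUE-ZR-3 and IUE-ZR-5 turns when at least 5 UMIs are asked for (12.3% and 12.6%), so no order is read between those 2 tumours. Free RNA from other cells was not tested as a source of these UMIs.

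Oligodendrocyte precursor-like cells, compared with the other neural cells of the same tumour in IUE-ZR-2, IUE-ZR-4 and IUE-ZR-5, had 14 of 25 G2M genes higher, and 9 of 15 matrix, 10 of 16 imprinted and 10 of 16 NF-kB genes lower. Ccnd1 averaged 1609 against 520 CPM (log2 fold change 1.51 ± 0.268 SE, n = 3 tumours, edgeR adjusted p 0.0051, higher in 3 of 3). The glial transcription factor Sox9 averaged 9.58 against 329 CPM, Icam1 5.30 against 156 CPM, Fn1 11.9 against 567 CPM and the growth factor Igf2 28.0 against 1027 CPM. Of 197 list genes tested 86 passed, 28 higher and 58 lower (88 over the lists alone). The 28 became 12 with doublets kept or at resolution 0.5, where IUE-ZR-6 also held enough of these cells (25 and 120), so the class and the tumours changed together, and 47 without IUE-ZR-4. G2M genes had 14 of 25 higher, such as cyclin B1 (Ccnb1, 124 against 28.3 CPM). PLAG family and imprinted genes had 1 higher and 10 lower of 16, such as Dlk1 (35.7 against 1218 CPM), NF-kB targets 0 and 10 of 16, mesenchymal genes 3 and 9 of 15 with Serpine2 (480.5 against 40.01 CPM) higher, and ZFTA-RELA genes 1 and 8 of 15. Stress genes had 2 higher and 7 lower of 16, hypoxia genes 1 and 6 of 18, Notch genes 3 and 4 of 13 with the ligand gene Dll3 (32.5 against 1.47 CPM) higher, interferon genes 1 and 2 of 16, MHC class I genes 0 and 2 of 10, S phase genes 1 and 1 of 25 and cholesterol genes 1 and 0 of 15. Rela averaged 16.2 against 45.2 CPM (edgeR adjusted p 0.0033). Whether these cells belong to the tumour was not tested.

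In oligodendrocyte-like cells of the same 3 tumours, G2M genes had 25 of 25 lower and S phase genes 24 of 25, with the topoisomerase gene Top2a at 10.5 against 206 CPM (log2 fold change -4.52 ± 0.387 SE). Ccnd1 averaged 57.1 against 562 CPM (log2 fold change -3.58 ± 0.393 SE, edgeR adjusted p 1.6e-04). Cholesterol synthesis genes had 12 of 15 higher, such as Hmgcs1 (465.5 against 131 CPM). Of 193 list genes 142 passed, 27 higher and 115 lower (150 over the lists alone). The 27 became 17 without IUE-ZR-2 and 14 without the tumour block. For this class too, it was not tested whether the cells belong to the tumour. Interferon genes had 6 higher and 1 lower of 16, with Ifi27l2a at 258 against 28.2 CPM, and mesenchymal genes 1 and 11 of 15, with S100a6 (770.4 against 54.3 CPM) higher. ZFTA-RELA genes had 1 higher and 11 lower of 13, imprinted genes 1 and 10 of 15, stress genes 0 and 11 of 16, NF-kB targets 0 and 9 of 16, MHC class I genes 1 and 5 of 10, Notch genes 3 and 5 of 12 and hypoxia genes 2 and 6 of 18, with Ndrg1 (114.5 against 22.2 CPM) higher.

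In astroglial-like cells of IUE-ZR-4, IUE-ZR-5 and IUE-ZR-6, 0 of 198 list genes passed in edgeR, 19 had an unadjusted p under 0.05, and 6 passed in DESeq2. The hyaluronan receptor gene Cd44 averaged 153.5 against 42.4 CPM (edgeR adjusted p 0.168), Vim 2421 against 1219 CPM and Cdkn1c 2778 against 605 CPM. Without IUE-ZR-6, 10 genes passed, and 28 with clusters at resolution 2. In IUE-ZR-4 the chromosome 7 median, against the same class of the other tumours, was -0.06 in 46 oligodendrocyte precursor-like cells, -0.003 in 37 oligodendrocyte-like cells and -0.03 in 24 astroglial-like cells. These cells lacked the shift of the neural sums of that tumour (-0.90 against the mean of IUE-ZR-3 and IUE-ZR-5). There, the class comparisons may therefore set cells from outside the tumour against tumour cells.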

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

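The test of low-UMI barcodes was chosen after the result was seen, and the test of doublets before. Of 37 values over the 5 tumours, 6 had 1 tumour far from the rest, at a gap to the nearest tumour of more than 0.71 of the range, which chance alone gives for about 1 group in 20. Astroglial-like cells held 26.2% of IUE-ZR-5 against 0.121 to 2.34% of the other tumours, a value that depends on the clustering (1596 cells, against 567 at resolution 2 and 216 with genes centred within each number). It also depends on the naming rule. The 2.34% of IUE-ZR-6 leaves out 1873 cells of cluster 8 and 699 of cluster 14. These clusters had 7 and 6 astroglial markers but stayed unnamed for 7 macrophage and 5 fibroblast markers. Neutrophil-like cells held 1.80% of IUE-ZR-4 against 0 to 0.359% elsewhere. Gcg, Glra2 and Zdbf2 stood highest in IUE-ZR-6, at 0.0455, 0.273 and 0.683 CPM, against at most 0.00557, 0.0613 and 0.233 CPM in the other tumours. The floor of that library is 0.137 CPM, so the first lies under it.

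Macrophage-like cells held 78.1% of IUE-ZR-4 against 2.15 to 17.0% of the other tumours, although GFP-positive cells were sorted. The lower shares leave out unnamed cluster 1 of IUE-ZR-3 (4331 cells, 13 macrophage markers) and cluster 8 of IUE-ZR-6 (1873 cells, 7 macrophage markers). Doublets of macrophages and tumour cells would carry tumour transcripts, but the named genes of that tumour had a median level in macrophage-like cells of 0.9754% of that in neural cells. Shallow barcodes do not make up the share either, since it was 75.5% among barcodes with at least 5000 UMIs. A gate that let unlabelled cells through, or GFP taken up by macrophages, may account for it and was not tested, as GFP was not analysed here. The design offers no group that would test a biological explanation.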

How the results depend on the processing

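The alternatives below were fixed before the data were examined, except the minimum of 5000 UMIs per cell, which was chosen after the results were seen, as were the relaxed rule for classes and the simulated folds of 5 and 8. Among the alternative values of the main counts, 97 stayed within 1.5 times or, for the G2M share, under the threshold (exact permutation p 0.00357 to 0.0357), and 25 counts moved beyond 1.5 times. The order of IUE-ZR-3 and IUE-ZR-5 in the G2M share turned without thinning (64.75% and 64.83%) and with at least 5 UMIs (12.3% and 12.6%). Between tumours and P4 brain the 175 genes became 3410 with DESeq2, 25 with all cells (which adds macrophages), 411 with sums thinned to the P4 total, and 0 to 1178 with 1 tumour left out. The lowest values came without IUE-ZR-3, IUE-ZR-4 and IUE-ZR-5 (0 each), then IUE-ZR-2 (4), and the highest without IUE-ZR-6 (1178). At least 5000 UMIs per cell gave 119, where the 94 higher genes became 60, and neuronal-like cells gave 172 higher, with IUE-ZR-5 and IUE-ZR-6 as the only tumours that held enough of them, so the class and the tumours changed together. The counts of 6504 and 4997 genes for IUE-ZR-3 against IUE-ZR-4 and IUE-ZR-5 became 4211 and 3178 with glmTreat, by its stricter construction, and 6508 became 4353 for IUE-ZR-4 against IUE-ZR-5. With all cells the 3109 genes lower in IUE-ZR-3 than IUE-ZR-4 became 4756 and the 2594 higher in IUE-ZR-4 than IUE-ZR-5 became 4304. Leaving out each library gave 6108 to 6526, 4691 to 4975 and 6048 to 6253. Same-numbered libraries did not deviate together (correlations -0.0455 to 0.0596), so the numbers do not pair the samples, and the replicate block gave 6402, 4821 and 6363. For astroglial-like cells the 0 list genes became 6 with DESeq2, 28 at resolution 2, 8 with genes centred within each number and 0 to 10 with a tumour left out (10 without IUE-ZR-6). At resolutions 0.5 and 2 only 2 tumours held enough oligodendrocyte-like cells, so those settings gave no value for that class. The lists passing camera, 10, 9, 10 and 8 of 15 in the 4 comparisons, became 0 in each with an estimated correlation, and 15 and 14 with fry for IUE-ZR-4 against IUE-ZR-3 and IUE-ZR-5. The 9 classes that differed between tumours became 3 to 8 with a library of IUE-ZR-3 or IUE-ZR-4 left out, lowest without replicate 1 or 2 of IUE-ZR-4 (3). Those tests also had fewer arrangements (210 instead of 560). Except where a construction is named, the cause was not tested. For named genes 1488 of 1613 values kept their side of the threshold, 122 lost it (121 of them against the P4 brain), 3 gained it and 0 reversed. The split of the 6 libraries of IUE-ZR-3 and IUE-ZR-4 into their numbers gave 6504 genes and was the only 1 of 10 splits to do so. The highest of the others gave 0, but each of those mixed both tumours within a group, which widens the spread, so the contrast decides nothing. In addition, 10 splits are too few for a share under 0.05. Depth sets the floor of 0.434 CPM in the P4 brain, against which folds of genes at 0 there are lower bounds.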

Other observations

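Among the tests and values in this part, those of chromosome 7 in macrophage-like cells and in its 20 Mb bins were chosen before their results were seen, and the others after. Macrophage-like cells also differed between tumours. With edgeR, 2167, 1218 and 2132 of 12868 genes passed for IUE-ZR-3 against IUE-ZR-4, IUE-ZR-3 against IUE-ZR-5 and IUE-ZR-4 against IUE-ZR-5. Most of these cells came from clusters 16 and 19 in IUE-ZR-3, clusters 0 and 2 in IUE-ZR-4 and clusters 13 and 19 in IUE-ZR-5. The interferon-inducible gene Ifit2 stood at 680 ± 25.8 CPM (n = 3) in IUE-ZR-4, 161 ± 28.8 (n = 3) in IUE-ZR-3 and 187 ± 46.1 (n = 2) in IUE-ZR-5, and Isg15 at 666 ± 14.6, 308 ± 24.4 and 221 ± 32.4 CPM. Of 16 interferon genes 6 were higher in IUE-ZR-4 than in IUE-ZR-3 and 5 than in IUE-ZR-5. Of 15 mesenchymal and matrix genes 8 were higher and 2 lower in IUE-ZR-3 than in IUE-ZR-4, with Spp1 at 2253 ± 228 against 137 ± 10.4 CPM and Fn1 at 202 ± 19.1 against 69.6 ± 2.61 CPM. Neural cells of the same tumours held more Spp1, 15483 and 2436 CPM (687% and 1774% of the macrophage level), and the part of these matrix transcripts that came from tumour RNA was not determined. Of 25 G2M genes 17 were higher in IUE-ZR-4 than in IUE-ZR-5 and 3 than in IUE-ZR-3. H2-Eb1, an MHC class II gene, reached 2.77% of the level of H2-Ab1 in macrophage-like cells of IUE-ZR-5, against 44.7% in IUE-ZR-2, 92.5% in IUE-ZR-3, 121% in IUE-ZR-4 and 52.7% in IUE-ZR-6.

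Within IUE-ZR-3, cluster 9 (1648 cells, 13.1% ± 2.26 of a library, n = 3) and cluster 4 (2570 cells, 20.4% ± 2.89) differed in the medians of several gene lists. S phase genes had a median log2 ratio of 0.70 in cluster 9 (19 of 19 higher) and G2M genes 0.97 (10 of 11), while hypoxia genes stood at -0.89 (1 of 17 higher) and MHC class I genes at -0.997 (0 of 9). Chromosome 4 had a median of -0.79 in the same contrast, with 8 bins between -0.90 and -0.76. Within IUE-ZR-5, the astroglial-like cluster 10 (1559 cells) stood above cluster 11 (1579 cells) in interferon genes, with a median of 1.95 (14 of 15 higher), in MHC class I genes, with 1.20 (10 of 10), and in dissociation and stress genes, with 1.19 (14 of 16), and below it in S phase (-1.02) and G2M genes (-0.90). These clusters were chosen after their values were seen and come from the same libraries, so no test was made. Of 380 chromosome medians over 20 neural tumour clusters with at least 5000 UMIs, 3 reached a size of 0.5. These were chromosome 4 in cluster 9 of IUE-ZR-3 and chromosome 7 in clusters 3 and 17 of IUE-ZR-4. Smaller shifts included chromosome 4 at -0.414 and -0.429 in clusters 22 and 23 of IUE-ZR-3. Cluster 20 of IUE-ZR-3 had chromosome 19 at 0.423. In cluster 11 of IUE-ZR-5, chromosome 10 stood at -0.312 and chromosome 3 at 0.229.

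Genes of chromosome 7 were lower in neural cells of IUE-ZR-4, by a median of -0.90 ± 0.032 on the log2 scale. A strain or donor variant would be shared by all cells of the animal, but macrophage-like cells of the same libraries had a median of -0.065. The other autosome that moved most had 0.144. The ratios were centred on the autosomal median beforehand, which removes a uniform scaling error, so this value cannot test scaling. The highest median among 8 bins of 20 Mb was -0.826, so the shift ran along the whole chromosome, as the hypothesis of 1 missing copy predicts. It lay in unnamed clusters 3, 17 and 34 of IUE-ZR-4, with -0.753, -0.839 and -0.481 against the median of the 5 tumours. Named classes lacked it, with -0.059 in oligodendrocyte precursor-like, -0.003 in oligodendrocyte-like and -0.026 in astroglial-like cells against the same class elsewhere. The hypothesis is therefore limited to cells of those unnamed clusters. Cdkn1c and H19, expressed from the maternal copy in mouse, stood at 2.72 and 10.1 CPM, while Igf2 and Kcnq1ot1, expressed from the paternal copy, stood at 1060.0 and 1082 CPM.

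Of 16 interferon genes 9 were higher and 2 lower in neural cells of IUE-ZR-4 than of IUE-ZR-3, and 3 of 10 MHC class I genes were higher. Neither list passed camera with an estimated correlation (adjusted p 0.279 and 0.415). RNA released by the many macrophage-like cells of IUE-ZR-4 could contribute even after a sort for GFP. The share of macrophage RNA in its neural sums, estimated from 16 markers, was 1.85%. At that share a median of 14.64% of the difference was given over 12 passing genes (4.04 to 95.4%, highest for Ifit2), between the limits set for and against this source. The markers themselves were not clearly higher in IUE-ZR-4, with a median ratio of 1.069 to IUE-ZR-3 (0.578 to 3.86, higher for 9 of 16). The neural sums of IUE-ZR-3 include its 4331 cells of cluster 1, with 13 macrophage markers among the 100 leading genes of that cluster, so the ratio does not compare free RNA alone. Macrophage RNA as a source therefore stays open, and a biological difference between the tumours was not tested by the design.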
